A study of Mus musculus with 6 samples.

How the data were processed

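Retinas were dissected from newborn wildtype and cyclin D1 knockout mice and pooled, and total RNA was purified with a column kit, labelled with biotin after 1 round of amplification and hybridised to Affymetrix arrays, per the labels' protocols. The labels number 3 pools of each genotype, and the replicate numbers come from the same titles as the genotypes. Nothing in the labels says how many animals were in a pool or whether litters were shared between pools, so p-values measure the spread between these pools. The deposited table holds 1 intensity value per probe set and array on a linear scale. The program that summarised probes and the scaling of the deposited intensity values are not given in the sources used here, and no detection calls were used, so no bound from background can be given.

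Per the labels, the submitters tested differential expression with the NIA Array Analysis tool, taking the larger of an average and a Bayesian error variance (window of 200 probe sets, the highest 1% of variances removed, 5 Bayesian degrees of freedom) at a false discovery rate of 0.1. They kept the probe set with the largest difference for each gene and only genes with binding data. The binding data were not used here.

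The table has 45101 probe sets, of which 64 controls were left out. Of the rest, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed, and only the first kind was used. Symbols of 34741 probe sets were brought up to date through their Entrez identifiers with RefSeq gene names of assembly GRCm38.p6. That table was used only for names and gene order, and no coordinates are given, since the array annotation names no build. No column of the table was left unused.

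Median log2 intensity ran from 5.34 to 5.66 between arrays, beyond the tolerance of 0.1 fixed beforehand, so the linear values were quantile normalised. They were floored at 1 and taken to log2(value + 16), and folds are on this scale, which understates the change of dim genes. Each gene was represented by the probe set with the highest mean over the 6 arrays, and the lowest 40% of genes (7277) were not tested. The remaining 10916 genes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), knockout against wildtype with no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.1 as in the labels. At a threshold of 0.05, 127 genes were higher and 195 lower, and at an unadjusted p under 0.05 there were 729 and 747. Figures were drawn with matplotlib 3.10.9.

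Before the data were examined, 22 gene lists, the test designs, most alternative settings and the rule for naming genes were fixed. The rule names Ccnd1, Notch1, Ccnd2 and Ccnd3, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, and up to 4 called members with the smallest p from each list that passed. Hes5, Lhx2, Id3, Dapl1, Mip, Mest, Col9a1, the genes near Ccnd1 and the members of the 2 added lists were named outside this rule, after their values were seen. Lists with at least 5 tested members (20 of 22) were tested with camera at its preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry. Of the 20, 11 passed with the preset correlation, 5 with an estimated one and 11 with fry, which asks only whether the genes of a list move one way. Some genes, such as Ptf1a, Btg2 and Dkk3, belong to several lists, so the lists are not independent of each other. The red blood cell list and the list of Y-linked genes with Xist had too few tested members. Of 577 symbols in the lists, 35 had no named probe set here. Genes near Ccnd1 were compared with all others by Fisher's exact test.

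Arrays were compared before averaging. The SD of the log2 difference between arrays was 0.22 for wildtype pools 1 and 2 and 0.21 for knockout pools 1 and 2, and 0.28 to 0.52 for every other pair. The labels name separate pools, so all 6 arrays were kept as samples. Whether pools 1 and 2 of a genotype share tissue or RNA is not known. If they do, fewer than 3 independent samples per genotype stand behind each SD, p-value and count of genes. The ratio of 3' to 5' beta-actin control signal was 1.49 to 2.22. A split of the tested genes showed 2 sets of 3 arrays, which were then defined by rank on the mean of the 5 BioB and BioC hybridisation control probe sets, and 1 of the other 4 control probe sets did not overlap between the sets. A fit with the set as a block was added after the data were seen, as was a fit with pools 1 and 2 of each genotype averaged.

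Alternatives covered the scaling between arrays, the pseudocount and floor, the filter on dim genes, the choice of probe set, the variance model, the submitters' error model written from its stated settings, the threshold, the replicate number as a block and leaving out each array. For array weights the default estimate of limma did not converge, so its gene-by-gene method was used instead, a change made after the default result had been seen. Both tests were checked on simulated data for this comparison, with 200 of 10916 genes changed in each of 10 runs. The simulated noise was independent between arrays, which left out the likeness of pools 1 and 2 and the sets of arrays. The rates below therefore hold for independent arrays and do not show the rate of false calls on the real ones. limma recovered 25.4% of changes of 0.5 on the log2 scale, 74.2% of changes of 1 and 96.7% of changes of 2, with 9.20% false calls. The error model recovered 2.54%, 59.1% and 98.3%, with 5.13% false calls. The degrees of freedom of its t statistic are not stated, and residual plus prior degrees of freedom (9) were assumed in these runs.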

Results

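Gene expression was measured in retinas dissected from newborn mice that lacked cyclin D1 and from wildtype newborns. Cyclin D1, encoded by Ccnd1, is a regulatory subunit of the kinases that carry cells from G1 into S phase. Each genotype was represented by 3 separately numbered pools of retinas, and each pool was hybridised to 1 Affymetrix expression array, giving 6 arrays. The submitters asked whether genes bound by cyclin D1 are turned up or down when the protein is missing. The list of bound genes was not used here, so the comparison below covers every gene that could be tested. Of 18193 genes named by a probe set, 10916 were bright enough to be tested. The median deposited signal of an array ranged from 40.6 to 50.5 units, and the number of arrays limits the precision. Levels are given as log2 of the normalised signal plus 16, as mean ± SD with n = 3 pools, and differences are knockout minus wildtype.

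The arrays also differed in a way that genotype does not account for. BioB and BioC hybridisation controls, bacterial transcripts added to every sample before hybridisation, were brighter on 3 arrays (wildtype pool 3 and knockout pools 1 and 2) than on the other 3 (wildtype pools 1 and 2 and knockout pool 3). The signal of 1 BioB control probe set ran from 641 to 809 units on the first set and from 555 to 609 on the second. Both sets hold both genotypes, so differences are given below within each set and with the set as a block wherever they bear on a result. Each within-set difference compares 1 array of one genotype with 2 of the other. Wildtype pool 3 is alone of its genotype in the first set and knockout pool 3 in the second. A within-set value therefore rests on a single array of one genotype and is a weak check. The sets were noticed from a split of the tested genes and then ranked on these controls.

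Ccnd1, on chromosome 7, was much lower in the knockout pools, and its relatives Ccnd2 and Ccnd3 were higher there. The Ccnd1 signal was 12.45 ± 0.10 in wildtype and 8.86 ± 0.05 in knockout retinas, a fall of 12-fold (log2 difference -3.59, SE 0.08, limma adjusted p = 5.78e-07). All 3 Ccnd1 probe sets showed it, with log2 differences from -4.24 to -3.59, and all 6 pools lay on the side their label names. Ccnd2, another D-type cyclin, rose 3.44-fold, from 7.07 ± 0.27 to 8.85 ± 0.13 (adjusted p = 0.00152), and its 5 bright probe sets differed by 0.49 to 2.04. Ccnd3 rose 2.35-fold, from 7.20 ± 0.34 to 8.43 ± 0.17 (adjusted p = 0.0129). Cdk6, a kinase partner of the D-type cyclins, rose 1.90-fold (adjusted p = 0.00310). Notch1, the receptor of a pathway that keeps retinal cells in the progenitor state, fell 1.77-fold, from 9.97 ± 0.09 to 9.14 ± 0.15 (adjusted p = 0.00609), and both of its probe sets were lower. With pools 1 and 2 of each genotype averaged, which leaves 2 samples per genotype, the calls of Ccnd3, Cdk6 and Notch1 ended (adjusted p = 0.195, 0.126 and 0.160, the largest over their alternatives). Within the sets of arrays the log2 difference of Ccnd1 was -3.73 and -3.48, that of Ccnd2 2.16 and 1.48, that of Ccnd3 1.71 and 0.85, and that of Notch1 -0.83 and -0.71, the set with brighter controls first.

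**Figure D1:**
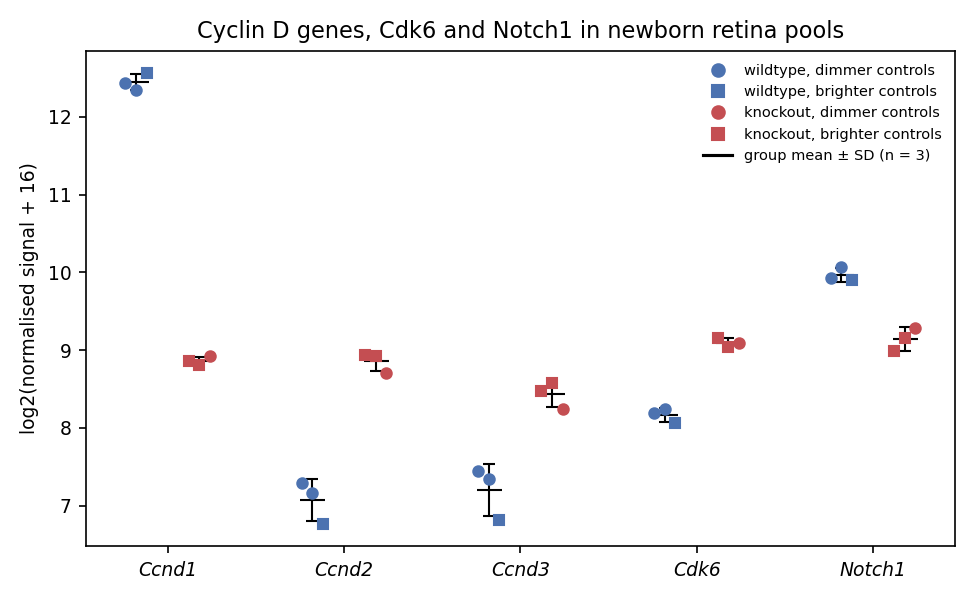
Log2 of the normalised signal plus 16 (vertical axis) of Ccnd1, Ccnd2, Ccnd3, Cdk6 and Notch1 in each of the 6 pools. Blue marks are wildtype and red marks knockout pools, squares are the 3 arrays with brighter hybridisation controls and circles the other 3, and bars give the group mean ± SD (n = 3); Ccnd1 drops from 12.45 to 8.86 while Ccnd2 goes from 7.07 to 8.85.

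Across the tested genes, 222 were higher and 287 lower in knockout retinas at the submitters' false discovery rate of 0.10. Crystallin genes, which encode the main structural proteins of the lens, made up 8 of the 10 largest rises: Crygd, Cryab, Crygb, Crygf, Cryga, Cryba4, Crybb1 and Cryaa, led by Crygd (7.94-fold). The other 2 were Aldh1a1, an enzyme of retinoic acid synthesis, which rose 6.87-fold from 8.58 ± 0.36 to 11.36 ± 0.13 (adjusted p = 0.000837), and Prss56, a serine protease gene, which rose 6.21-fold (adjusted p = 0.0176), with log2 differences of 3.63 and 1.34 within the sets with brighter and dimmer controls. Over 21 alternatives Prss56 lost its call in 2 (without knockout pool 1 and with pools 1 and 2 of each genotype averaged), Cryba4 in 8, Crybb1 in 6 and Crygd, Crygb and Crygf in 5 each. After Ccnd1, the largest falls were those of Ptf1a, a transcription factor needed for amacrine and horizontal cells (5.29-fold, from 7.94 ± 0.34 to 5.54 ± 0.12, adjusted p = 0.00108), and Arhgap11a (3.76-fold). Crabp1, which binds retinoic acid, fell 3.30-fold, the proliferation marker Mki67 3.12-fold and the amacrine cell factor Tfap2b 2.98-fold. Tubb6, Zfp367, Cenpf and Prdm8 completed the 10 largest falls, with log2 differences from -1.50 to -1.36. For Tubb6 and Cenpf, 1 of 2 bright probe sets showed no fall (0.04 and 0.02), and Tubb6 lost its call in 5 of 21 alternatives.

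Among the called genes, 60 rose and 63 fell by more than 2-fold. In all 509 the 3 knockout pools lay apart from the 3 wildtype pools, as they did in 2182 of the 10916 tested genes. Chance alone gives 10% only where all arrays are equally unlike. Pools 1 and 2 of each genotype were more alike than other pairs, so that share is no yardstick here. A called gene has a small spread for its difference, so its groups lie apart almost by selection. With the set of arrays as a block, 597 genes were higher and 433 lower, and these included all 222 and all 287 of the genes above. The set was found in these same values, so a block on it lowers the residual spread. What is left rests largely on the differences between pools 1 and 2 of each genotype, the most alike pairs. The larger counts are therefore no support for the genotype calls. With pools 1 and 2 of each genotype averaged, which gives the same log2 differences as the block, 17 genes were higher and 26 lower. In the values as deposited, without scaling between arrays, 70.3% of calls were rises against 43.6% here, and the median difference of all genes was 0.13 against 0.02. The count depended strongly on single arrays, from 68 higher and 99 lower without knockout pool 1 to 862 higher and 1055 lower without wildtype pool 3. Of 54 genes named by a rule fixed beforehand, 37 lost their call with averaged pools, and 15 of these in no other alternative.

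Genes of mitosis and DNA replication formed the largest group of falls. Of 45 tested mitosis genes, 39 fell and none rose, with a median log2 difference of -0.96 (camera adjusted p = 1.89e-49; adjusted p = 0.0729 with an estimated correlation). Top2a, which untangles DNA before chromosomes separate, fell from 10.23 ± 0.07 to 9.06 ± 0.11 (log2 differences -1.17 and -0.34 in its 2 probe sets), Smc4, a condensin subunit, fell by 1.14 on the log2 scale, and Cdca8, of the chromosomal passenger complex, by 1.32. Of 41 DNA replication genes, 23 fell and none rose, with a median of -0.59 (camera adjusted p = 1.43e-30; 0.0614 as the adjusted p with an estimated correlation). Pcna, the sliding clamp of the replication fork, fell 1.75-fold, Mcm7, of the replicative helicase, 1.79-fold, Rrm2, of ribonucleotide reductase, 1.95-fold, and Uhrf1, which helps copy DNA methylation, 2.31-fold. There were 41 mitosis and 33 replication genes lower when adjusted over the list alone. The 39 and 23 became 25 and 13 without wildtype pool 1, 22 and 11 without knockout pool 1, 23 and 12 without knockout pool 2, 23 and 13 with the replicate number as a block, and 6 and 3 with pools 1 and 2 of each genotype averaged, which leaves 2 samples per genotype. Replication genes lower were 10 with arrays centred on their medians and 35 with array weights. The mitosis median was -0.90 and -0.85 within the sets with brighter and dimmer controls, and the replication median was -0.51 and -0.63.

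Cell cycle regulators moved in both directions. Of 31 tested, 3 rose (Ccnd2, Ccnd3 and Cdk6) and 9 fell, among them Ccna2, the cyclin of S and G2 phases, which fell 2.57-fold from 10.15 ± 0.05 to 8.79 ± 0.19 (adjusted p = 0.00108). The list's median was -0.07 (camera adjusted p = 0.000113; adjusted p = 0.0729 with an estimated correlation), and adjusted over the list alone 3 were higher and 13 lower. Its medians within the sets were -0.32 and -0.16, brighter controls first, and Ccnd1 itself is a member. There were 6 higher and 13 lower without wildtype pool 3, 8 and 14 with array weights and 1 and 3 with averaged pools. The median was -0.19 without wildtype pool 3, -0.03 without wildtype pool 1 and 0.01 with values as deposited, where the test still pointed down. The list of retinal progenitor genes showed no shift as a whole, with 7 of 29 members higher and 3 lower, a median of 0.01 and a camera adjusted p of 0.531. In this list 8 genes were higher and 6 lower when adjusted over the list alone. The 7 became 3 without wildtype pool 1 or 2 or knockout pool 3, 2 without knockout pool 1 or 2 and 1 with averaged pools, and without wildtype pool 3 there were 7 higher and 7 lower. Of 32 Notch pathway genes 2 were lower, Notch1 and Hes5, a target of the pathway, and none was higher, also when adjusted over the list alone. Without wildtype pool 3 there were 2 higher and 4 lower, and with array weights 5 and 8. The Notch list had a median of 0.03, while its mean of -0.02 and its test pointed down (camera adjusted p = 0.765).

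The ganglion cell and photoreceptor lists shifted upward in knockout retinas and the amacrine and horizontal cell list downward, although most members of each did not pass the test. Of 26 ganglion cell genes, 6 rose and 1 fell, with a median log2 difference of 0.33 (camera adjusted p = 4.02e-08; adjusted p = 0.0614 with an estimated correlation). The synuclein gene Sncg rose 1.82-fold, the neurofilament gene Nefl 1.53-fold and Gap43, a protein of growing axons, 1.62-fold, whereas Nhlh2, a neuronal transcription factor, fell 2.45-fold. Of 28 photoreceptor genes, 4 rose and none fell, with a median of 0.33 (camera adjusted p = 2.29e-09; adjusted p = 0.158 with an estimated correlation). These were Pdc, phosducin, which rose from 10.13 ± 0.22 to 10.95 ± 0.06, the cone genes Gnb3 and Opn1sw, and the rod gene Pde6g, with log2 differences of 0.49 to 1.01. Over 21 alternatives Pde6g lost its call in 11, Gnb3 in 9 and Opn1sw in 7, and the difference of Opn1sw was 1.70 and 0.41 within the sets, brighter controls first, and 0.17 in its other bright probe set. Of 19 amacrine and horizontal cell genes, 6 fell and 1 rose, with a median of -0.34 (camera adjusted p = 0.00097; adjusted p = 0.0729 with an estimated correlation). This call ended when the lowest 60% of genes were left out (median -0.05, camera adjusted p = 0.108, the largest over the alternatives), and the median was -0.02 with array weights and -0.15 without wildtype pool 3. Beside Ptf1a and Tfap2b these included Meis2, which fell 1.80-fold, and Gad1, an enzyme that makes the transmitter GABA, which fell 1.76-fold.

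Adjusted over the list alone, 13 ganglion cell genes were higher and 2 lower, 13 photoreceptor genes higher and none lower, and 2 amacrine and horizontal cell genes higher and 6 lower. Within the sets, brighter controls first, the ganglion cell median was 0.38 and 0.29, the photoreceptor median 0.52 and 0.36, and the amacrine and horizontal cell median -0.38 and -0.26. The 4 photoreceptor genes higher became 17 with the set as a block, 12 with array weights, 9 with values as deposited, 2 with the replicate number as a block, 1 without an intensity trend and 0 with averaged pools. Without wildtype pools 2 and 3 they were 1 and 9, and without knockout pools 1, 2 and 3 they were 1, 1 and 2. The 6 ganglion cell genes became 11 with the set as a block, 18 with array weights and 1 with averaged pools, where 2 amacrine and horizontal cell genes were lower. Neurogenic precursor genes had 4 members lower and 1 higher of 23, a median of -0.18 and a camera adjusted p of 0.0343 (adjusted p = 0.158 with an estimated correlation). Neurog2, a proneural factor, fell 1.95-fold and Foxn4 1.43-fold, beside Ptf1a, and Btg2, an antiproliferative gene, rose 1.49-fold. The list's call ended with the lowest 60% left out (camera adjusted p = 0.214, the largest over the alternatives), 1 member was lower with the replicate number as a block or without wildtype pool 1 or 2 or knockout pool 1 or 2. Without wildtype pool 3 there were 8 lower and 3 higher (median -0.09), with array weights 10 and 6 and with the set as a block 9 and 3, and without wildtype pool 2 the median was -0.28. Over 21 alternatives Foxn4 lost its call in 10 and Neurog2 and Btg2 in 7 each. Adjusted over the list alone, 5 were higher and 8 lower, and the medians within the sets were -0.29 and -0.12.

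Muller glia genes had 4 members higher and 1 lower of 22, a median of 0.32 and a camera adjusted p of 0.00650 (adjusted p = 0.102 with an estimated correlation). Apoe, a lipid carrier, rose 2.16-fold, Glul, glutamine synthetase, 1.38-fold and Dkk3 1.28-fold, and Sox2, a factor also found in progenitors, fell 1.47-fold. Over 21 alternatives Dkk3 lost its call in 9, Glul in 7 and Sox2 in 4. The 4 glial genes higher became 9 without wildtype pool 3, 1 without wildtype pool 1 or knockout pool 1 or 2, and 0 with averaged pools. The list's median was 0.21 with the set as a block. Adjusted over the list alone, 8 were higher and 2 lower, and the medians within the sets were 0.11 and 0.34. Of 21 p53 target and apoptosis genes Btg2 rose and none fell, with a median of 0.17 and a camera adjusted p of 0.0569 (adjusted p = 0.158 with an estimated correlation). In that list 2 were higher and none lower when adjusted over the list alone, and the medians within the sets were both 0.12. The p53 list's call ended with the lowest 60% left out, with array weights and without wildtype pool 3 (camera adjusted p = 0.116, 0.133 and 0.158). Without wildtype pool 3 it had 5 members higher and 1 lower, with array weights 7 and 1, and without wildtype pool 2 or any 1 knockout pool no member was higher. Its median was 0.10, 0.11 and 0.09 without wildtype pool 2, wildtype pool 3 and knockout pool 2. No bipolar cell gene of 8 passed the test (median 0.07, camera adjusted p = 0.467). Immediate early and heat shock genes had 2 higher and 1 lower of 19, which became 5 and 2 without wildtype pool 3, none without knockout pool 1 or 2, and 1 and 0 without any 1 of the other pools. Their median was -0.02, while the mean of 0.11 and the test pointed up (camera adjusted p = 0.467).

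**Figure D2:**
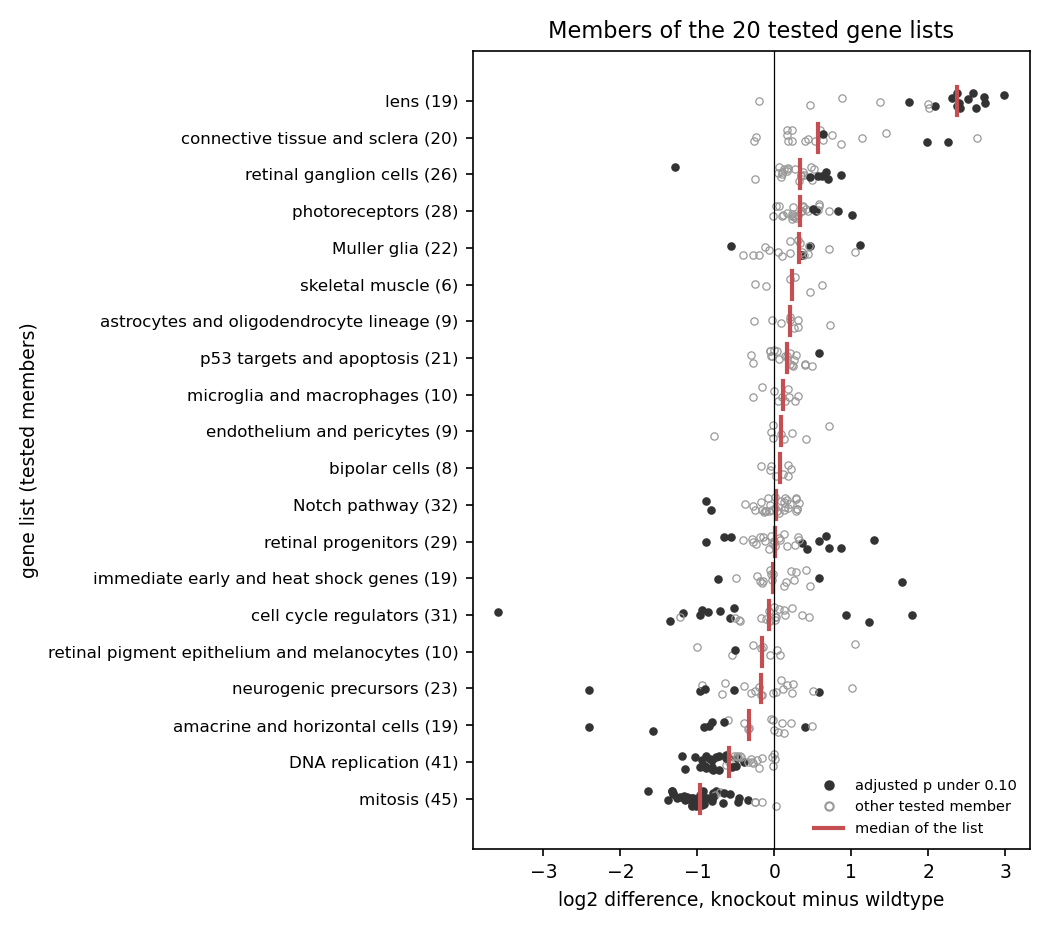
Log2 difference, knockout minus wildtype (horizontal axis), of each tested member of the 20 gene lists (vertical axis, number of tested members in brackets). Filled points have an adjusted p under 0.10, open points are the other members and red bars are list medians; the medians run from -0.96 for mitosis to 2.37 for lens.

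Lens genes were far higher in the knockout pools and varied widely within each genotype. Of 19 tested lens genes, 13 rose and none fell, with a median log2 difference of 2.37 (camera adjusted p = 1.82e-16; adjusted p = 0.158 with an estimated correlation), and adjusted over the list alone 18 were higher. Cryba1 rose from 10.37 ± 0.66 to 12.74 ± 0.49, Cryba2 from 8.28 ± 0.65 to 10.66 ± 0.68 and Cryab from 7.55 ± 0.87 to 10.30 ± 0.67. Lens genes held 0.0628% of the total signal in wildtype pool 3, 0.158% and 0.160% in wildtype pools 1 and 2, 0.456% and 0.436% in knockout pools 1 and 2, and 1.18% in knockout pool 3. These shares moved with genotype, as did the mitosis, replication, ganglion cell, photoreceptor, amacrine cell and glial groups. The lens median was 2.74 within the set with brighter controls and 2.72 within the other, and with the set as a block 17 lens genes were higher. That count was 1 with the replicate number as a block, 0 with averaged pools (median 2.76) and 6, 6 and 7 without knockout pools 1, 2 and 3.

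Connective tissue and sclera genes had 3 members higher and none lower of 20, a median of 0.56 and a camera adjusted p of 2.24e-06 (adjusted p = 0.269 with an estimated correlation). Sparc, a matrix protein, rose 3.95-fold from 8.35 ± 0.26 to 10.33 ± 0.09 (adjusted p = 0.000996), Pcolce, which helps process collagen, rose 1.55-fold, and Col1a1, a collagen chain, rose 4.76-fold with an adjusted p of 0.0997. There were 11 higher and 1 lower when adjusted over the list alone. Over 20 alternatives Pcolce lost its call in 10 and Col1a1 in 8, and the 3 genes higher became 9 without knockout pool 3 and 1 without any one of the other arrays except wildtype pool 3, where 6 were higher. The list's mean lay above the wildtype mean by 0.97 and 1.02 in knockout pools 1 and 2 and by 0.23 in knockout pool 3. Within the sets its median was 0.69 and 0.14, and the difference of Col1a1 was 3.51 and 0.49. The medians of the endothelial, microglial, astrocyte and oligodendrocyte, and skeletal muscle lists were 0.09, 0.12, 0.21 and 0.23, with camera adjusted p values of 0.454, 0.467, 0.166 and 0.320, and none of their members passed over all genes. Of their alternatives, 1, 0, 3 and 3 gave a camera adjusted p under 0.10, and without wildtype pool 3 each list had 1 member higher and the endothelial and astrocyte lists also 1 lower. Adjusted over the list alone, 2 endothelial genes were higher and 1 lower and no gene of the other 3 lists passed. The pigment epithelium list had 1 member lower of 10 (median -0.16, camera adjusted p = 0.100, just over the threshold), and 1 higher and 2 lower when adjusted over the list alone. It passed in 9 of 20 alternatives, over which the camera adjusted p ran from 0.0170 to 0.528. Without wildtype pool 3 it had 1 member higher and 3 lower, and without any 1 of the other pools except knockout pool 3 it had none.

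**Figure D3:**
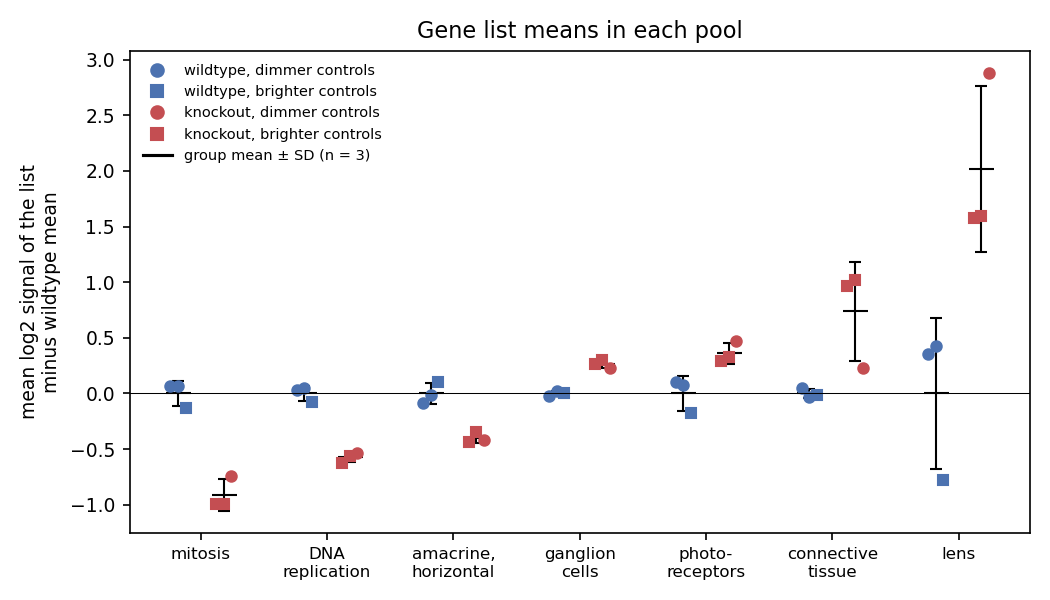
Mean log2 signal of 7 gene lists in each pool, minus the wildtype mean of the list (vertical axis). Blue marks are wildtype and red marks knockout pools, squares are the 3 arrays with brighter hybridisation controls and circles the other 3, and bars give the group mean ± SD (n = 3); lens genes reach 2.88 in knockout pool 3, against 1.58 and 1.60 in the other knockout pools.

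Genes beside Ccnd1 were compared with the rest because a targeted allele carries flanking chromosome from its strain of origin. Among tested genes within the nearest 200 annotated genes on each side of Ccnd1 on chromosome 7, 6 of 60 were called, against 502 of 10855 elsewhere. The odds ratio was 2.29 (95% interval 0.80 to 5.35, Fisher's exact test, two-sided p = 0.0594), so an excess was not established. It was 1.48 (exact p = 0.270) with the array set as a block, 3.03 (exact p = 0.0312) at an adjusted p under 0.05 and 2.93 (exact p = 0.0353) without knockout pool 3. The 6 genes, named because their count is small, were Ano1, Fgf15, Ifitm2, Igf2, Sct and Tspan4, and all were higher in knockout retinas. Fgf15, Tspan4, Ano1, Sct and Ifitm2 lost their call in 9, 7, 6, 4 and 1 alternatives. Igf2, a growth factor gene, rose 2.35-fold (adjusted p = 0.00177). On one side only 6 annotated genes lie between Ccnd1 and the end of the chromosome.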

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

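The fits with array weights by the gene-by-gene method, with the array set as a block and with averaged pools were chosen after seeing the data. Ccnd1 fell under every setting run, with log2 differences from -4.24 to -3.50. No gene named by the rule fixed beforehand reversed, and no list that passed reversed the direction of its test: over 1108 values of those genes and 220 values of the 11 lists under alternatives, 148 and 5 lost their call. Of 176 values of the 9 lists that had not passed, 16 gained a call, 9 of them in the pigment epithelium list. For 18 genes named outside the rule, 61 of 375 values lost their call and none reversed. The lack of reversals in named genes was largely fixed in advance and is no support. In every called gene the knockout pools all lay on one side of the wildtype pools. Dropping, averaging or weighting arrays therefore cannot turn its sign. The numbers of genes higher and lower, 222 and 287, moved widely. They were 416 and 176 with values as deposited, 118 and 121 with arrays centred on their medians, 1862 and 1747 with array weights, 88 and 120 with the submitters' error model at an assumed 9 degrees of freedom, and 127 higher at an adjusted p under 0.05. The error model with only its 4 residual degrees of freedom, run after seeing the data, called 0 higher and 1 lower, Ccnd1 (241 and 305 at an unadjusted p under 0.05). With the array set as a block 597 genes were higher and 433 lower, and with pools 1 and 2 of each genotype averaged 17 and 26, where only 2 samples stand for each genotype. Both fits give the same log2 differences, and only the first counts pools 1 and 2 as separate samples. Leaving out 1 array gave 68 to 862 higher and 99 to 1055 lower genes. The extremes were knockout replicate 1 and wildtype replicate 3, whose array weight was 0.154. With the replicate block there were 126 and 143. Deviations from the group means correlated across genes by 0.17, -0.35 and -0.48 between pools of the same number. They correlated by 0.55, 0.50, 0.20 and 0.16 between pools of different genotype that share an array set. Between wildtype pool 2 and knockout pool 1, and wildtype pool 1 and knockout pool 2, which do not share a set, they correlated by -0.37 and -0.48. The sets thus go with the sign of most of these values, which cannot show whether the numbers pair the samples. Camera with an estimated correlation passed 5 lists in place of 11. The odds ratio near Ccnd1 was 3.03 (Fisher's exact p = 0.0312) at an adjusted p under 0.05 and 2.93 (exact p = 0.0353) without knockout replicate 3; leaving out 1 array gave 1.71 to 3.19.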

Other observations

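The weighing of lens, mitosis and array set patterns below used tests chosen after the patterns were seen, except the comparisons of 2 probe sets per gene, the splits of the arrays and the added ciliary margin and imprinted gene lists, whose own values had not been seen.

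Col9a1, a collagen chain gene, rose 4.26-fold in knockout retinas, from 9.42 ± 0.03 to 11.51 ± 0.04 (limma adjusted p = 5.06e-06), beside the rises of Ccnd2, Aldh1a1 and Prss56. Col9a1 and Ccnd2 are known from the ciliary margin, the rim where retina meets ciliary body. In an added list of 14 further margin genes, 7 could be tested and all 7 were higher, 2 of them past the threshold: Wfdc1 rose 2.21-fold and Rdh10, a retinol dehydrogenase gene, 2.37-fold. Their median log2 difference was 0.31 (camera p = 8.73e-05; p = 0.0156 with an estimated correlation). The median falls to 0.21 when 1 member is left out, below the 0.3 set in advance, so a larger share of margin in the knockout pools stays open as a hypothesis.

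Progenitor genes moved apart within their list. Id3, an inhibitor of neurogenic factors, rose 2.45-fold and Dapl1 1.82-fold, while Hes5 fell 1.84-fold and Lhx2, an eye field transcription factor, 1.58-fold (no call in 3 alternatives). Mest, an imprinted gene, rose 4.55-fold beside Igf2. In an added list of 13 other imprinted growth genes, 10 of 11 tested were higher and 3 passed: Plagl1, Gnas and Grb10, which lost their call in 6, 10 and 11 alternatives. Their median was 0.20 (camera p = 0.000128; p = 0.0159 with an estimated correlation), between the values set in advance for a shared rise and for none, so the hypothesis of a group-wide rise stays open.

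The split of the 6 arrays by hybridisation control brightness called 954 genes, against 509 for the split by genotype. These are the only 2 of the 10 splits that keep pools 1 and 2 of each genotype together, and every other split called 0. The counts therefore cannot tell a difference tied to the controls apart from the likeness of those pools. A difference in RNA content is argued against for most single genes outside the lens list: in 4154 genes with 2 bright probe sets the set difference of one probe set hardly matched that of the other (correlation across genes 0.14), whereas the genotype difference did (0.66), and where the set difference was over 0.5 its sign agreed in 53.4% of genes, against 91.1% for genotype. For mitosis, photoreceptor and connective tissue genes it stays open: their lists differed between the sets by medians of 0.25, 0.24 and -0.34, dimmer minus brighter, and in 40 members the 2 probe sets correlated by 0.47 (95% interval 0.18 to 0.68). Hybridisation or scanning cannot be told apart from other array differences, because the sets were ranked on 5 of the 9 hybridisation control probe sets and only 1 of the other 4 lay apart. In the count of genes higher, 222 by genotype, and of genes lower, 287, the highest other split had 725 in 1 direction, so 2 of the 10 splits reached each count. With 10 splits no share under 0.05 can be reached. The blocked counts were 597 and 433, but the block is that other split itself, so they do not bear on chance. Averaged pools gave 17 and 26.

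Lens genes were higher in the knockout pools. Scaling is argued against by a median difference of at least 2.37 under all 3 scalings. A rise of crystallins alone in retinal cells is argued against only weakly by the 6 other lens genes. Their median difference was 1.12 (0.88 to 1.37 when 1 member is left out). Camera gave p = 0.000548 for them, but p = 0.121 with an estimated correlation. Hsf4 was at -0.20 and only Mip passed, with no call with the replicate number as a block or averaged pools. With the array set as a block 4 of the 6 passed, but with averaged pools no gene of the lens list did. Lens tissue carried into the pools may account for the pattern, but this was not settled. Of 19 members, 17 were lowest in wildtype pool 3 and highest in knockout pool 3, with Cryba1 and Cryaa at 13.29 and 13.19 in the latter. The pools were picked after their lens signal was seen, and lens genes move together (estimated correlation 0.74). The 2.11 members that chance gives for unlinked genes are therefore no yardstick. Lens genes that change together for any reason would give the same count. Wildtype pool 3 and knockout pool 3 also stand alone of their genotype in their array sets. Whether knockout eyes are harder to dissect or differ in the lens was not tested.

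Mitosis and DNA replication genes were lower in the knockout pools. Scaling is argued against by a mitosis median no higher than -0.85 under the 3 scalings. Dilution by lens or connective tissue RNA would lower all retinal genes alike, but the ganglion cell and photoreceptor lists together had a median of 0.33. Loss of progenitor cells and nothing else would lower progenitor genes as much as mitosis genes, but the progenitor median lay 0.97 above the mitosis median, beyond the spread of its members (median absolute deviation 0.42), although several of those genes are also made in glia. A smaller share of dividing cells among the progenitors, or earlier exit from the cell cycle, may remain as a hypothesis, and neither cell numbers nor ages within the day of birth were measured here.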
